A study of Mus musculus with 20 samples.

How the data were processed

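RNA from mouse spinal cord was measured on 20 two-colour oligonucleotide arrays. Each array paired 2 animals, one labelled with Cy5 and the other with Cy3. The animals were wild type (WT) mice or littermates carrying a GFAP-IkappaBalpha-dn transgene (TG), a construct that blocks NF-kappaB signalling in astroglia. They were naive or had experimental autoimmune encephalomyelitis (EAE), an induced inflammatory disease of the central nervous system, at 10, 17 or 80 days post-induction (dpi). The labels name 23 animals, 3 in each of the 8 groups except WT at 17 dpi, where only animals 1 and 4 are named. The design text instead states 3 animals at every time, so a number on these labels can be wrong, and n = 2 here, like each fit without animal 1 or 4, follows the labels as they stand.

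The authors deposited 1 log ratio per feature and array for 44290 features, taken here as log2. That base is not stated by the file. It was read from the use of limma and from the range of the values, which reach 7.80. Per the labels' design text, the authors normalized each array by global loess and then between arrays by the quantile algorithm in limma. The scanner, background correction and any filter on dim probes are not given in the sources used here, and the deposited ratios carry no signal level, so dim and bright probes could not be told apart. Each array held between 43710 and 43894 values, with medians between -0.02 and 0.02. The number of arrays, not a read depth, limits the precision.

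The direction of the deposited ratios is not stated either. The plan fixed before the data were examined was to read each as Cy5 over Cy3, the order of the titles. That plan carried 2 checks. By 1 of them, dye-swapped TG and WT arrays of 1 time were to correlate negatively as deposited. They did in naive mice (-0.732 and -0.785), at 10 dpi (-0.659 to -0.602) and at 80 dpi (-0.356 to -0.289), but at 17 dpi gave -0.0479 and 0.238. A dye effect in ratios read as TG over WT gives negative values too, so this cannot tell the readings apart. The other check, on the 4 arrays that pair an EAE animal with a naive animal of its genotype, failed on 2 of the 4. By the plan, failure on some arrays leaves the directions unsettled. The ratios were instead read as TG over WT, EAE over naive, and, on the arrays without naive animals, WT at 17 dpi over 80 dpi and TG at 80 dpi over 17 dpi. This reading was chosen after the values were seen. It is a working direction, not a stated one, and the plan's rule leaves it unsettled. It rests on 3 comparisons of the values. First, the MHC class II median was then above 0 on all 4 of those arrays (1.97, 0.23, 0.58 and 0.40). The check on these arrays also held T cell markers (0.08 to 0.36) and macrophage and microglia markers (0.15 to 1.96). Choosing the reading by these 3 lists means that their direction on those arrays is not independent evidence of inflammation. Second, the part of the TG and WT arrays that turned with the dye was compared with the arrays of 1 genotype that shared no animal with them. It correlated over probes at 0.474 and 0.536 for the naive set, and for the 17 dpi set at 0.411, 0.434 and 0.0708 where the first-named group of the ratio was in Cy5 and at -0.364 where it was in Cy3. For the 80 dpi set the values were 0.172 in Cy5 and -0.411 in Cy3. Last, the pooled log-likelihood of the model was higher by 57709 than in title order, and turning any 1 array lowered it for 19 of the 20. The exception was the 10 dpi array of TG animal 1-5 and WT animal 1-4. The sums of the ratios round closed loops of 4 and of 8 arrays went the other way, with spreads over genes of 0.783 and 1.62 as used and of 0.318 and 0.887 in title order. The dye effect enters those sums 4 and 8 times in either reading. With the dye effect of the arrays outside each loop taken off, the spreads were 0.364 and 1.02 as used and 0.536 and 1.42 in title order. Of the list medians examined in the uncorrected sum of 4, only that of T cell markers lay nearer 0 in title order (0.04, and 0.23 as used). Nearer 0 as used were skeletal muscle genes (0.29, and 2.72 in title order), red blood cell genes (-0.17, and 1.65), macrophage and microglia markers (-0.07, and 0.44) and MHC class II genes (0.40, and 0.47). In the sum of 8 only MHC class II genes lay nearer 0 in title order (0.60, and 0.67 as used). The loops hold 12 of the 20 arrays, of which 5 are read differently in the 2 readings, and none of the TG and WT arrays at 10 or 17 dpi. For the 10 dpi arrays the second comparison was undecided, with correlations from -0.009 to 0.14.

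Each probe was fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0) by generalised least squares. The model held a coefficient per group and a dye effect per probe. Arrays that share an animal were allowed 1 common correlation, estimated by pooled restricted maximum likelihood at 0.01 (0.04 for genes). Moderated tests used empirical Bayes with 13 residual and 1.92 prior degrees of freedom. Probes with a value on at least 16 arrays were tested, 43778 in all. Of the others, 511 were left out by that minimum and 1 lacked arrays for a term. P-values were adjusted by Benjamini-Hochberg within each comparison, and calls are at an adjusted p under 0.05. The standard errors (SE) are those of the fit, and n counts animals. Because the correlation is 1 value for all probes, SEs and p-values can be too small for genes that vary more between animals. The 10 comparisons were TG against WT at each of 4 times and the contrasts of naive, 17 and 80 dpi within a genotype. A further 4 interaction terms tested whether TG minus WT differed between times. No array links the 10 dpi animals to those of other times, so EAE at 10 dpi could not be set against naive animals within a genotype.

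Symbols came from the platform's annotation table. Of the features, 32042 had 1 symbol, 47 had several and 12201 had none in the table used here. An Entrez identifier matched a current gene for 31906 probes, and 0 symbols changed. For gene lists, probes were averaged per gene, which gave 19086 genes. Values of list members are therefore gene averages and can differ from the probe values given elsewhere. The 28 lists of cell types and pathways, with 678 entries, were written before the data were examined. Of the entries, 53 were not named in the table used here and 4 were updated to a current symbol. Lists were tested with cameraPR at a preset inter-gene correlation of 0.01, in families of 280 tests for the comparisons and 112 for the interactions, and again with the correlation estimated from the residuals. That second p is larger in most of the tests, and most list calls are lost with it. Of 250 list calls at the preset correlation, 76 are described in the text or shown in its figures. Across the 10 comparisons, lists called at the preset correlation numbered from 3 to 24. With an estimated correlation, calls were left only for TG against WT at 80 dpi (3), WT at 80 dpi against naive (3) and TG at 80 dpi against naive (2).

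Named genes followed a rule set in advance. For each comparison these were the 10 probes with 1 symbol that were highest and the 10 that were lowest among those past the threshold, 1 probe per gene. Where fewer than 5 passed, the 5 with the most extreme moderated statistic are given as not passing. Up to 4 members of a list with the largest absolute statistic serve as examples, and for interactions the 5 probes with the smallest p. Nfkbia and Gfap were always included.

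The fit was tested on simulated data, with 200 of 43207 probes changed. For TG against WT in naive mice, 46.8% of probes changed by 0.5 on the log2 scale were recovered, 79.7% of those changed by 1 and 92.8% of those changed by 2, and 5.73% of calls were false. At 10 dpi these shares were 50%, 78.8%, 93.9% and 3.90%. At 17 dpi they were 56.7%, 77.9%, 94.4% and 4.91%, and at 80 dpi 54.4%, 82.3%, 95.7% and 4.91%. Simulated correlations of 0, 0.3 and 0.6 were recovered as such. The shares of recovered probes and of false calls describe the simulated data only. The real arrays differed in spread, with SDs from 0.286 to 1.07, and in fitted array weight, from 0.0389 to 9.56. The simulated shares therefore need not hold for the real arrays. Alternatives fixed in advance treated arrays as independent, dropped the dye term, recentred or rescaled arrays, changed the probe minimum, used robust moderation or array weights, averaged probes per gene, used only the arrays that pair the groups compared, or left out each animal in turn. After the data were seen 4 more were added: title order for all arrays, title order at 10 dpi, a dye term of its own at 10 dpi, and the fit without 3 TG animals with high skeletal muscle genes.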

Results

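Spinal cord RNA of 12 TG and 11 WT mice was compared on 20 two-colour arrays. TG mice express a dominant negative IkappaBalpha under the promoter of the astrocyte gene Gfap, and the comparisons ask how blocking astroglial NF-kappaB changes gene expression in healthy cord and during EAE. One TG and 1 WT animal were paired on 3 arrays for naive mice, 4 for 10 dpi, 3 for 17 dpi and 4 for 80 dpi. A further 6 arrays, 1 each, paired times within a genotype. Each contrast of times within a genotype therefore has 1 direct array and otherwise rests on links through other groups. Its n counts the animals of the 2 groups, not pairs that were compared. Each array gave values for 43710 to 43894 features. All values are log2 ratios or log2 fold changes with the standard error of the fit. The labels do not settle which animal of an array is the numerator. The directions below are those of the reading described with the processing. The plan's rule leaves them unsettled, and they are least secure at 10 dpi.

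The label genes were examined first. Nfkbia encodes IkappaBalpha, but its probe need not detect the transgene, so it is a limited check. Its deposited ratio, TG over WT, was 0.06, 0.47 and -0.04 on the naive arrays and -0.13, -0.48, 0.10 and 0.36 at 10 dpi. At 17 dpi it was -1.22, 1.39 and -0.96, and at 80 dpi -0.50, -0.60, -0.62 and -0.41. No fold change of Nfkbia between TG and WT passed at any time (0.31 ± 0.31 in naive mice, -0.04 ± 0.30 at 10 dpi, -0.48 ± 0.31 at 17 dpi and -0.48 ± 0.27 at 80 dpi). Gfap, which encodes the intermediate filament of astrocytes, was measured by 3 probes. They did not pass in naive mice (0.03 ± 0.21, 0.00 ± 0.27 and 0.10 ± 0.16), at 10 dpi (-0.35 ± 0.21, -0.84 ± 0.26 and -0.50 ± 0.15) or at 17 dpi (0.06 ± 0.21, 0.07 ± 0.27 and -0.05 ± 0.16). At 80 dpi Gfap was lower in TG by 2 of the probes (-0.86 ± 0.19, adjusted p = 0.0297, and -1.08 ± 0.24, adjusted p = 0.0303), and the third gave -0.54 ± 0.14 (adjusted p = 0.0744). On single arrays the ratios of Gfap ran from -0.32 to 0.98 in naive mice, from -1.84 to 0.69 at 10 dpi, from -0.46 to 0.71 at 17 dpi and from -1.29 to -0.29 at 80 dpi.

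In naive mice no gene separated TG from WT cord (n = 3 and 3). The highest by moderated statistic were Setdb1, a histone methyltransferase (0.76 ± 0.15), Gtf2ird1 (0.22 ± 0.05), Prkcb (0.30 ± 0.07), 4930568E12Rik (2.16 ± 0.52, on 2 of 3 arrays) and Rc3h2 (0.54 ± 0.13). The lowest were Zkscan3 (-0.42 ± 0.06), Vsnl1 (-0.80 ± 0.19), Lhfp (-0.20 ± 0.05), Smc6 (-0.63 ± 0.17) and Cisd2 (-0.22 ± 0.06). None of these passed, and the smallest adjusted p was that of Zkscan3 at 0.369. limma called 0 of 43778 probes, and 458 had an unadjusted p under 0.05. Myelin and oligodendrocyte markers had a median of -0.13 over 29 measured genes, and of -0.0782 without WT animal 2. Mal (-0.44 ± 0.18) and Tspan2 (-0.42 ± 0.17) were among their most extreme members, and 0 members passed, also when adjusted over the list alone. The list's own test gave an adjusted p of 3.43e-07 at the preset correlation and an adjusted p = 0.187 with an estimated correlation. With array weights 251 probes were called, and with the naive arrays alone 133.

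At 10 dpi the antiviral RNA sensor Ddx58 was lower in TG than in WT cord (-0.80 ± 0.10, adjusted p = 0.0371, n = 3 and 3), as was the chromosome maintenance gene Smc6 (-1.09 ± 0.17). The pannexin Panx3 (-1.32 ± 0.18) was called lower from 1 array only, that is from 1 TG and 1 WT animal. Lratd1 was higher (0.97 ± 0.15, adjusted p = 0.0438). The signs of Ddx58, Smc6 and Lratd1 held on 4 of 4 arrays. TG animal 1-5 and WT animal 1-4 are each on more than 1 of them, so these are not 4 replicates. Next in order, and not passing, were Tmprss11g (0.43 ± 0.07), the insulin-responsive glucose transporter Slc2a4 (0.83 ± 0.15), Peg10 (0.66 ± 0.12), Ppp1r17 (0.28 ± 0.05), the cell cycle cyclin Ccnd2 (-0.56 ± 0.09) and H2ac1 (-0.48 ± 0.08). Interferon response genes had a median of -0.70 over 37 genes. Irf8 (-0.78 ± 0.21) and Bst2 (-1.20 ± 0.32) were examples, 0 members passed over all genes and 26 were lower when adjusted over the list alone. The 41 macrophage and microglia markers had a median of -0.46, with Fcgr1 at -1.20 ± 0.26 and C1qa at -0.98 ± 0.21, and 14 lower when adjusted over the list alone. Among 21 inflammatory chemokines, with a median of -0.55, Ccl2 was at -1.99 ± 0.40 and Cxcl10 at -3.22 ± 0.69, and 6 were lower when adjusted over the list alone. Skeletal muscle genes had a median of 1.23 over 16 genes, with Actn3 at 1.75 ± 0.50 and Ckm at 1.90 ± 0.65. Those 4 lists passed at the preset correlation (adjusted p = 2.56e-30, 9.65e-24, 2.31e-14 and 1.0e-15) and lost the call with an estimated correlation (adjusted p = 0.155, 0.119, 0.123 and 0.155). The immune lists were set apart by 1 array, that of TG animal 1-3 and WT animal 10-4, where the interferon median was -2.20 against -0.46 to 0.04 on the other 3. Without either of its animals the interferon, macrophage and microglia, and chemokine medians were -0.23, -0.10 and -0.12. Without TG animal 1-5 they were -1.22, -0.78 and -0.91, and without WT animal 1-4 -1.07, -0.75 and -0.87. The muscle list was set apart by TG animal 1-5, whose 2 arrays gave 2.97 and 2.72 and without which the median was -0.19 (0.50 without WT animal 4-3).

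In all, 6 probes were higher and 6 lower at 10 dpi, with 2855 at an unadjusted p under 0.05. The count was 0 without the dye term, with a separate dye term at 10 dpi, with probes averaged per gene and on the 10 dpi arrays alone. Scaling the arrays raised it. Leaving out TG animal 1-5 or WT animal 1-4 raised the count to 44 and 43, and leaving out TG animal 1-2 or WT animal 4-3 gave 6 and 7. Read in title order instead, the 10 dpi arrays gave 487 probes higher and 1821 lower, and the signs of Lratd1, Ddx58, Smc6 and the immune lists turned.

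At 17 dpi genes of antigen presentation and of macrophages were lower in TG than in WT cord (3 TG and 2 WT animals by the labels, 3 by the design text, 3 arrays). The lowest were Arg1, an arginase of activated macrophages (-3.94 ± 0.45, adjusted p = 5.9e-05), the chitinase-like Chil4 (-3.79 ± 0.23), the MHC class II chains H2-Aa (-3.75 ± 0.37) and H2-Ab1 (-3.69 ± 0.39), lysozyme Lyz1 (-3.55 ± 0.44) and the T cell chemokine Ccl5 (-3.45 ± 0.42). They were followed by the interferon-induced GTPase Tgtp1 (-3.33 ± 0.49), AW112010 (-3.26 ± 0.45), Tgfbi (-3.25 ± 0.40) and the phagocyte glycoprotein Gpnmb (-3.25 ± 0.30). Higher in TG were Lratd1 (2.02 ± 0.15, adjusted p = 6.22e-06), the haemoglobin chains Hbb-bt (1.80 ± 0.24) and Hba-a1 (1.73 ± 0.29), Mcf2 (1.70 ± 0.50), Rspo4 (1.52 ± 0.42), Ak5 (1.40 ± 0.36), Ccl25 (1.39 ± 0.43), the myelin gene Mobp (1.35 ± 0.27), the neutrophil alarmin S100a9 (1.34 ± 0.39) and the tubulin regulator Stmn1 (1.30 ± 0.32). These signs held on 3 of 3 arrays except for Rspo4, which kept its sign on 2 of 3 and was at -0.16 without WT animal 4. Those arrays hold TG animals 3 and 7 and WT animals 1 and 4. TG animal 7 and WT animal 4 are each on more than 1, so these are not 3 replicates. The genes were also chosen by their fold changes in a fit that includes these arrays. The size of several of the higher genes differed between arrays. With the dye effect taken off they ran from 0.32 to 4.50 for Mcf2, 0.13 to 4.03 for Ccl25, 0.51 to 3.36 for Ak5, 0.38 to 3.26 for Stmn1, 0.73 to 3.01 for Mobp, 0.23 to 2.36 for S100a9 and -0.22 to 3.18 for Rspo4, while Lratd1 ran from 1.76 to 2.41 and Arg1 from -4.17 to -3.88.

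By list, 35 of 41 macrophage and microglia markers were lower in TG at 17 dpi (35 adjusted over the list alone, median -1.36), among them Cd84 (-2.06 ± 0.20), the complement chain C1qb (-1.73 ± 0.17) and Trem2 (-1.55 ± 0.16). MHC class I and antigen processing genes were lower in 17 of 21 (20 adjusted over the list alone, median -1.55), with H2-Q2 at -2.37 ± 0.23 and H2-T22 at -1.55 ± 0.15. MHC class II genes were lower in 8 of 10 (9 adjusted over the list alone, median -2.01). Of 37 interferon response genes 25 were lower (32 adjusted over the list alone, median -1.19), including Gbp4 (-2.66 ± 0.36) and Ifi47 (-2.70 ± 0.38). Inflammatory chemokines were lower in 9 of 21 (13 adjusted over the list alone), such as Cxcl9 (-3.14 ± 0.36), and complement genes in 8 of 14 (8 adjusted over the list alone), such as Cfb (-3.21 ± 0.35) and Serping1 (-2.88 ± 0.32), with 1 complement gene higher. T cell markers were lower in 10 of 27 (11 adjusted over the list alone), with Nkg7 at -1.70 ± 0.21. NF-kappaB feedback and target genes were lower in 9 of 28 (12 adjusted over the list alone), led by Sod2 (-1.01 ± 0.12), Cebpb (-1.48 ± 0.27) and Relb (-0.66 ± 0.14). Reactive astrocyte genes were lower in 11 of 35 (17 adjusted over the list alone, 1 higher), including Gbp2 (-2.16 ± 0.29) and Psmb8 (-2.23 ± 0.34), both also interferon-induced. The median of reactive astrocyte genes (-0.40) was -0.22 without TG animal 1, -0.15 without WT animal 1 and -0.80 without WT animal 4. That of NF-kappaB genes (-0.35) was -0.0827 without WT animal 1 and -0.58 without WT animal 4, and that of T cell markers (-0.19) was -0.11 without TG animal 7 and -0.38 without WT animal 1. Neuronal markers were higher in 12 of 36 (14 adjusted over the list alone), with Uchl1 at 0.74 ± 0.09 and Calb2 at 0.91 ± 0.14, and red blood cell genes in 5 of 7 (6 adjusted over the list alone). Each of these 11 lists passed at the preset correlation. With an estimated correlation none of them did (adjusted p = 0.103 for macrophage and microglia markers, 0.119 for MHC class I, 0.15 for MHC class II, 0.212 for interferon response, 0.261 for chemokines, 0.123 for complement, 0.311 for T cell markers, 0.338 for NF-kappaB genes, 0.359 for reactive astrocyte genes, 0.212 for neuronal markers and 0.155 for red blood cell genes). Ribosomal protein genes were lower in 14 of 39 (17 adjusted over the list alone, median -0.31), with Rplp0 at -0.85 ± 0.09, and cell cycle genes in 9 of 25 with 1 higher (12 and 1 adjusted over the list alone, median -0.25), with Bub1b at -1.06 ± 0.16. Myelin and oligodendrocyte markers were higher in 8 of 29 and lower in 2 (11 and 2 adjusted over the list alone, median 0.21), with Olig2 at 0.39 ± 0.08. These 3 calls were lost with an estimated correlation (adjusted p = 0.3, 0.277 and 0.516). The ribosomal median was -0.19 without TG animal 3, -0.49 without WT animal 1 and -0.0657 without WT animal 4, and the myelin median 0.0531 without WT animal 1 and 0.39 without WT animal 4.

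At 17 dpi limma called 1989 probes higher and 3689 lower in TG. The count was 2796 without TG animal 1, 10113 without TG animal 7 and 11748 without WT animal 1, and the 3 arrays alone gave 0 calls. Title order also gave 0 calls, and the macrophage and microglia and MHC class II medians then turned to 0.15 and 0.0973. The array of TG animal 3 and WT animal 4 had the widest spread of all 20 (SD 1.07, others 0.286 to 0.730).

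**Figure D1:**
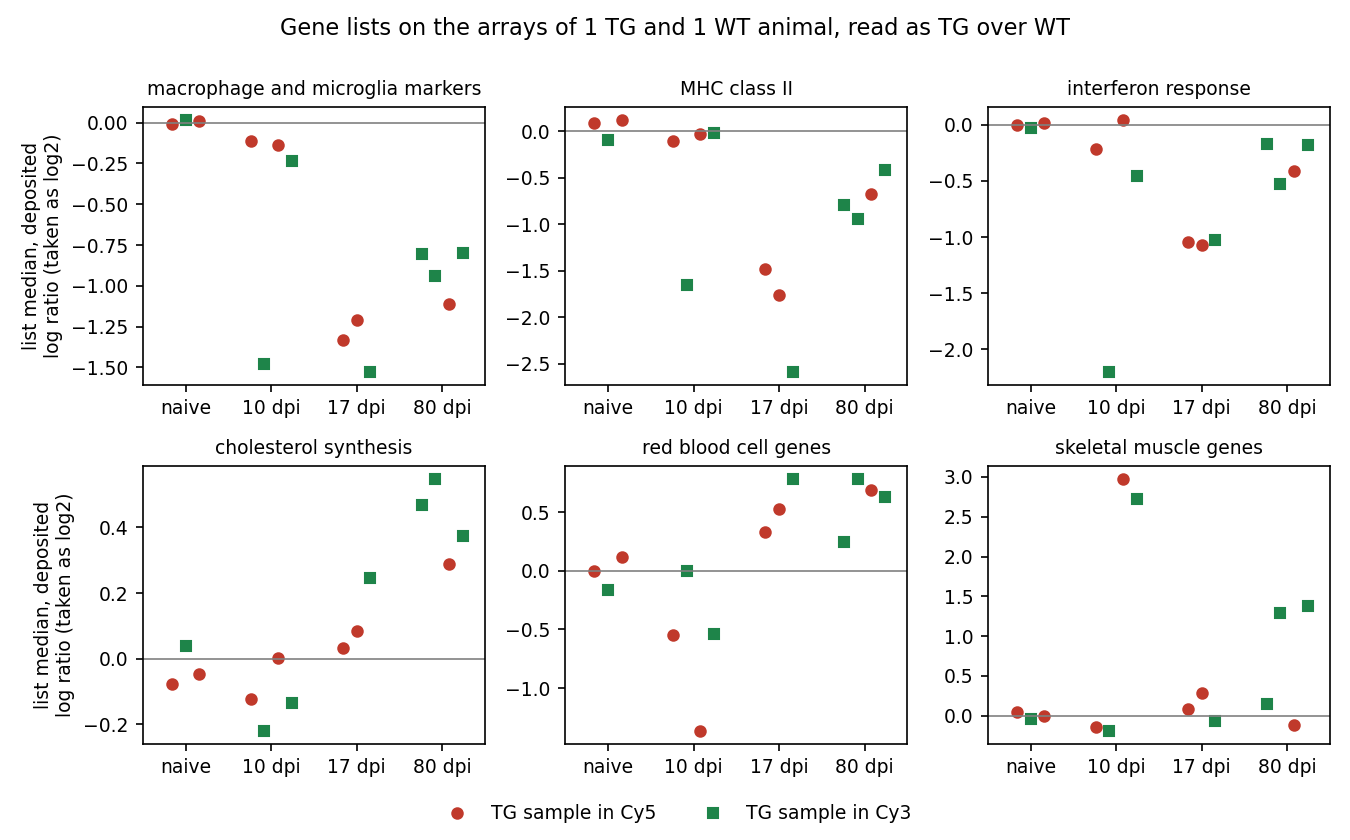
Median deposited log ratio of 6 gene lists on each array of 1 TG and 1 WT animal, read as TG over WT; the vertical axis is taken as log2, the horizontal axis is time, and circles and squares mark arrays with the TG sample in Cy5 and in Cy3. Macrophage and microglia medians lie from -1.53 to -1.21 at 17 dpi and from -1.11 to -0.80 at 80 dpi in both dye orientations, with -0.01 to 0.02 in naive mice.

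At 80 dpi microglial and macrophage genes were the lowest in TG relative to WT, while genes of cholesterol synthesis were higher (n = 3 and 3, 4 arrays). The phagocyte genes Gpnmb (-4.16 ± 0.27, adjusted p = 1.84e-06), Lyz1 (-3.06 ± 0.39), Lyz2 (-2.61 ± 0.28) and Trem2 (-2.32 ± 0.18) led, with the lysosomal proteases Ctsd (-2.28 ± 0.16) and Ctss (-2.27 ± 0.32). The signalling adaptor Tyrobp (-2.16 ± 0.20), the complement chains C1qa (-2.15 ± 0.19) and C1qc (-2.13 ± 0.15) and the MHC class II chain H2-Ab1 (-2.15 ± 0.34) completed the lowest 10. Higher in TG were Insig1 (1.15 ± 0.17), the sterol pathway enzymes Hmgcs1 (1.15 ± 0.15, adjusted p = 0.00048), Idi1 (1.05 ± 0.14), Cyp51 (0.99 ± 0.20), Fdps (0.98 ± 0.12) and Msmo1 (0.64 ± 0.10), and the cholesterol carrier Stard4 (1.00 ± 0.14). Hbb-bt (1.07 ± 0.22), Lratd1 (0.89 ± 0.13) and the neurofilament gene Nefm (0.73 ± 0.17) were higher as well. All 20 kept their sign on 4 of 4 arrays. TG animal 26 and WT animal 15 are each on more than 1 of them, so these are not 4 replicates.

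Of 41 macrophage and microglia markers 25 were lower in TG at 80 dpi (35 adjusted over the list alone, median -1.0), and of 20 cholesterol synthesis genes 15 were higher (19 adjusted over the list alone, median 0.39), with Nsdhl at 0.59 ± 0.08 and Sqle at 0.56 ± 0.08. Neuronal markers were higher in 7 of 36 (12 adjusted over the list alone, median 0.29), among them the neurofilament Nefh (0.65 ± 0.13) and Calb2 (0.64 ± 0.13). These 3 lists passed both at the preset correlation and with an estimated correlation (adjusted p = 0.0289, 0.0161 and 0.0319). Reactive astrocyte genes were lower in 6 of 35 (9 adjusted over the list alone), including Serpina3n (-2.13 ± 0.35), Vim (-0.87 ± 0.15) and Serping1 (-1.63 ± 0.28), and their call was lost with an estimated correlation (adjusted p = 0.212). Astrocyte homeostatic markers were lower in 8 of 29 and higher in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.103 with an estimated correlation), with Id3 at -0.81 ± 0.07, the metallothionein Mt2 at -0.92 ± 0.10, the apolipoprotein Apoe at -1.32 ± 0.20 and Slc7a10 at 0.48 ± 0.08. Extracellular matrix and scar genes were lower in 5 of 29 (13 adjusted over the list alone; adjusted p = 0.0963 with an estimated correlation), such as Postn (-0.54 ± 0.06) and Col6a1 (-0.79 ± 0.09). Lower members of other lists were Cd74 (-1.80 ± 0.33) among 5 of 10 MHC class II genes, C4b (-1.77 ± 0.23) among 6 of 14 complement genes and Ccl3 (-1.59 ± 0.21) among 3 of 21 chemokines, with 7, 6 and 6 adjusted over the list alone. Those 3 calls were lost with an estimated correlation (adjusted p = 0.144, 0.118 and 0.267), and the chemokine median (-0.32) was -0.49 without TG animal 27 and -0.58 without WT animal 14. Ribosomal protein genes were lower in 7 of 39 (20 adjusted over the list alone, median -0.28), with an adjusted p of 6.34e-22 at the preset correlation and 0.123 with an estimated one. Over 19006 genes the fold changes correlated with genomic gene length at 0.102 (Spearman). Skeletal muscle genes had a median of 0.73 with 0 members passing and 0 adjusted over the list alone, and red blood cell genes were higher in 2 of 7 (5 adjusted over the list alone; adjusted p = 0.118 with an estimated correlation). On single arrays the muscle median was 1.29 for TG animal 21 and 1.38 for TG animal 27, and 0.15 and -0.12 on the arrays of TG animal 26. Without TG animals 21, 27 and 1-5 it was -0.03, and without TG animal 26 it was 1.25.

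At 80 dpi 98 probes were higher and 628 lower in TG. Leaving out any 1 of the 6 animals lowered the total, to between 158 (TG animal 26) and 333 (WT animal 14). Without TG animals 21 and 27 at 80 dpi and TG animal 1-5 at 10 dpi, 0 probes were called. Read in title order, the 20 genes named above turned their sign, as did the medians of macrophage and microglia markers (0.42), cholesterol synthesis genes (-0.21) and neuronal markers (-0.29). Of the probes lower in TG at 17 and at 80 dpi, 395 were the same, where independent lists would share 52.9, and of those higher, 34, where 4.45 would be shared. Linked arrays enter both estimates, so part of that excess can come from shared error.

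**Figure D2:**
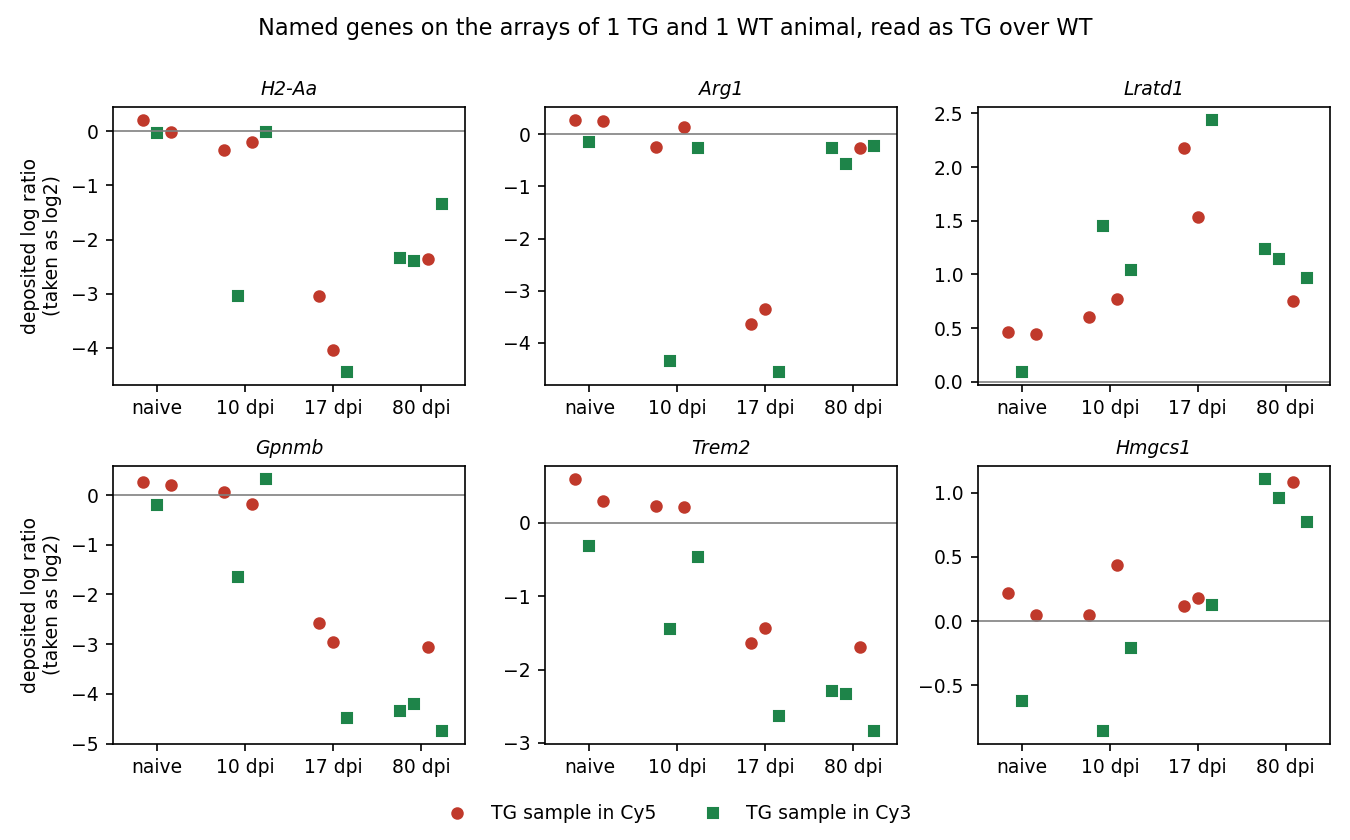
Deposited log ratio of 6 named genes on each array of 1 TG and 1 WT animal, read as TG over WT; the vertical axis is taken as log2, the horizontal axis is time, and circles and squares mark arrays with the TG sample in Cy5 and in Cy3. Gpnmb lies between -4.75 and -3.06 at 80 dpi, Hmgcs1 between 0.77 and 1.11, and Lratd1 is above 0 on all 14 arrays.

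Against naive WT cord, WT cord at 17 dpi showed a rise of chemokine, interferon and antigen presentation genes (n = 2 and 3). The highest were the chemokine Cxcl10 (5.38 ± 0.93, adjusted p = 0.0012), the interferon-induced GTPases Iigp1 (4.78 ± 0.83), Gbp3 (4.52 ± 0.74) and Tgtp1 (3.94 ± 0.64), Lyz1 (4.45 ± 0.58), AW112010 (4.41 ± 0.59), Wfdc17 (4.2 ± 0.43), H2-Ab1 (4.17 ± 0.50), the cathepsin Ctsc (4.12 ± 0.52) and Arg1 (3.98 ± 0.59). Among the genes that fell were the synaptic gene Snap25 (-2.42 ± 0.42), Snhg11 (-2.49 ± 0.14, adjusted p = 1.08e-06), Ube2b (-2.37 ± 0.26), Ndrg4 (-2.26 ± 0.50) and Gm14461 (-2.80 ± 0.84). Vps26b (-2.20 ± 0.60), Lmtk2 (-2.16 ± 0.49), Lrpprc (-2.15 ± 0.68), Thoc2 (-2.13 ± 0.67) and Madd (-2.09 ± 0.67) fell as well. Gm14461 turned to 0.22 without WT animal 1 at 17 dpi and to 0.11 without naive WT animal 2. Macrophage and microglia markers rose in 35 of 41 (38 adjusted over the list alone, median 1.89), interferon response genes in 34 of 37 (35, likewise adjusted over the list alone, median 1.96) and MHC class I genes in 17 of 21 (20 adjusted over the list alone). Chemokine genes rose in 13 of 21 (15 adjusted over the list alone, median 1.24) and MHC class II genes in 8 of 10 (8 adjusted over the list alone, median 1.79). Ribosomal protein genes rose in 33 of 39 (35 adjusted over the list alone, median 0.79), with Rpl35 at 1.61 ± 0.18 and Rplp0 at 1.12 ± 0.12. Neuronal markers fell in 17 of 36 (19 adjusted over the list alone), including Uchl1 (-1.30 ± 0.12), and myelin and oligodendrocyte markers fell in 13 of 29 and rose in 2 (18 and 2 adjusted over the list alone), including Mbp (-0.99 ± 0.19) and Olig2 (-0.66 ± 0.11). With an estimated correlation these 8 lists lost their calls (adjusted p = 0.103, 0.187, 0.123, 0.157, 0.157, 0.125, 0.119 and 0.271 in the order given). In all 3667 probes rose and 3391 fell. The total was 983 without naive WT animal 2, 2090 without WT animal 1 at 17 dpi and 12775 without WT animal 4. Without WT animal 1 the interferon median was 1.29, the ribosomal median 1.31 and the myelin median -0.11 (-0.56 with it), and without naive WT animal 2 the myelin median was -0.26 and the chemokine median 0.72. In title order 0 probes were called and the macrophage and microglia median turned to -0.82. The macrophage and microglia and MHC class II lists helped choose the reading, so their rise in EAE here and below is not independent evidence.

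WT cord at 80 dpi still differed from naive WT cord (n = 3 and 3, with 1 array that pairs the groups). Naive WT animal 3 was paired only with naive TG animal 7, so no array sets it against an EAE animal. Lyz1 (5.00 ± 0.57), the neutrophil alarmins S100a8 (4.82 ± 0.43) and S100a9 (3.49 ± 0.50), Gpnmb (4.54 ± 0.38, adjusted p = 4.65e-05), Lyz2 (3.86 ± 0.41), the complement inhibitor Serping1 (3.42 ± 0.41), Cfhr2 (3.21 ± 0.46), H2-Ab1 (3.09 ± 0.50), the matrix gene Ogn (3.06 ± 0.34) and Wfdc17 (2.92 ± 0.42) rose. The sterol enzymes Hmgcs1 (-1.03 ± 0.21) and Fdps (-1.02 ± 0.17) fell, with the glucocorticoid-induced Sgk1 (-1.13 ± 0.25) and Tsc22d3 (-0.63 ± 0.12), the lipid transporter Mfsd2a (-0.93 ± 0.13), the neuronal genes Slc17a6 (-0.77 ± 0.17) and Gng3 (-0.77 ± 0.12), and Slc25a33 (-0.76 ± 0.17), Eef1a2 (-0.69 ± 0.13) and Kcnh1 (-0.63 ± 0.11). Macrophage and microglia markers rose in 23 of 41 (36 adjusted over the list alone, median 1.29), cholesterol synthesis genes fell in 2 of 20 (15 adjusted over the list alone, median -0.29) and neuronal markers in 1 of 36 (14 adjusted over the list alone, median -0.37). These 3 lists also passed with an estimated correlation (adjusted p = 0.0289, 0.0474 and 0.0319). In all 428 probes rose and 48 fell. The total was 58 without naive WT animal 4, 106, 184 and 271 without WT animals 14, 13 and 15 at 80 dpi, and 175 without naive WT animal 2. In title order 0 probes were called and the macrophage and microglia median turned to -1.31.

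Between 17 and 80 dpi in WT cord (n = 2 and 3) the highest were the growth factor Igf2 (4.65 ± 0.32, adjusted p = 6.15e-06), Ogn (2.82 ± 0.34), Hba-a1 (2.44 ± 0.37), Ube2b (2.32 ± 0.26), Pltp (2.31 ± 0.21), the retinol carrier Rbp4 (2.20 ± 0.24), Slc6a20a (2.15 ± 0.31), Sned1 (2.10 ± 0.19), Igfbp5 (2.10 ± 0.15) and the neutrophil granule gene Ngp (2.09 ± 0.39). Arg1 (-4.15 ± 0.58), Chil4 (-3.83 ± 0.30), Iigp1 (-3.52 ± 0.82), Tgtp1 (-3.44 ± 0.63), Cxcl10 (-3.40 ± 0.91), Ms4a8a (-3.32 ± 0.43), Gbp3 (-3.25 ± 0.73), AW112010 (-3.25 ± 0.59), Igtp (-3.24 ± 0.66) and Cxcl9 (-3.16 ± 0.46) fell. Interferon response genes fell in 20 of 37 (29 adjusted over the list alone), ribosomal protein genes in 21 of 39 (30 adjusted over the list alone) and cholesterol synthesis genes in 8 of 20 (15 adjusted over the list alone). Their calls at the preset correlation were lost with an estimated correlation (adjusted p = 0.212, 0.157 and 0.119). Probes that rose numbered 1667 and those that fell 1740. The total lay between 696 without WT animal 13 at 80 dpi and 7118 without WT animal 4 at 17 dpi. Without WT animal 1 at 17 dpi the interferon, ribosomal and cholesterol medians (-1.19, -0.52 and -0.44) were -0.72, -0.88 and -0.20.

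In TG cord at 17 dpi against naive TG cord (n = 3 and 3), the neutrophil genes S100a8 (4.2 ± 0.44, adjusted p = 0.000206) and S100a9 (2.94 ± 0.51) rose, with Cxcl10 (3.01 ± 0.92), Wfdc17 (2.20 ± 0.43), the leukocyte antigen Cd52 (1.81 ± 0.51), Cfhr2 (1.62 ± 0.47), Rbm3 (1.56 ± 0.27), Agbl4 (1.53 ± 0.42), Slirp (1.52 ± 0.30) and Rps27l (1.46 ± 0.22). The non-coding RNAs Snhg11 (-2.55 ± 0.14), Meg3 (-2.25 ± 0.23), Malat1 (-1.86 ± 0.44) and Mirg (-1.72 ± 0.27) fell, as did Ube2b (-2.44 ± 0.26), Ncdn (-1.98 ± 0.42), Ndrg4 (-1.91 ± 0.50), Lmtk2 (-1.79 ± 0.49), the glycine receptor Glra1 (-1.65 ± 0.38) and Phkg2 (-1.63 ± 0.12). Of the macrophage and microglia markers 7 of 41 rose (7 adjusted over the list alone, median 0.42), with Ly86 at 1.16 ± 0.32, and ribosomal protein genes in 20 of 39 (27 adjusted over the list alone, median 0.47; 1 member fell by that count). Neuronal markers fell in 10 of 36 (10 adjusted over the list alone). With an estimated correlation these calls were lost (adjusted p = 0.502, 0.238 and 0.267). In all 3000 probes rose and 4299 fell, but the total was 14 without TG animal 1, 36 without naive TG animal 5, 4154 without naive TG animal 8 and 11113 without TG animal 3. Without TG animal 1 the ribosomal median was 0.19. TG animals 1 and 5 share the only array that pairs the groups.

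At 80 dpi against naive (n = 3 and 3), TG cord had 8 probes that rose and 1 that fell, with 634 at an unadjusted p under 0.05. With array weights the count was far higher, as given with the settings below. S100a8 (4.95 ± 0.43), S100a9 (3.51 ± 0.50), Ogn (2.58 ± 0.34), the von Willebrand factor gene Vwf (2.11 ± 0.29), Igf2 (2.09 ± 0.23), Mgp (1.84 ± 0.23) and the collagen Col1a2 (1.06 ± 0.12) rose and Sgk1 fell (-1.66 ± 0.25, adjusted p = 0.0337). Arrdc2 (-1.23 ± 0.25), Hpca (-0.51 ± 0.11), Mfsd2a (-0.63 ± 0.13) and St3gal3 (-0.34 ± 0.08) did not pass. Neutrophil markers rose in 2 of 17 (6 adjusted over the list alone, median 0.32) and red blood cell genes in 0 of 7 (4 adjusted over the list alone, median 0.76), and both lists also passed with an estimated correlation (adjusted p = 0.0289 for each). The macrophage and microglia list had a median of 0.22 (0.33 without naive TG animal 8) with 0 of 41 passing and 0 adjusted over the list alone. Skeletal muscle genes had a median of 1.16 (adjusted p = 0.155 with an estimated correlation), and -0.07 without TG animals 21, 27 and 1-5. Without TG animal 27 or naive TG animal 8, the pair on the direct array, 1 probe was called in each case.

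TG cord at 80 dpi against 17 dpi (n = 3 and 3) had higher Igf2 (2.54 ± 0.23, adjusted p = 8.44e-05), Ogn (2.29 ± 0.34), Ube2b (2.33 ± 0.26), Meg3 (2.16 ± 0.22), Snhg11 (2.16 ± 0.14), the matrix gene Fn1 (1.86 ± 0.29), Slc6a20a (1.79 ± 0.31), Pltp (1.78 ± 0.21), Tbx1 (1.67 ± 0.22) and the muscle actin Acta1 (3.02 ± 0.84). Slirp (-1.61 ± 0.30), Timm8b (-1.49 ± 0.28), Pfdn4 (-1.36 ± 0.40), Rpl35 (-1.31 ± 0.18), Mrps18c (-1.27 ± 0.22), Rps27l (-1.26 ± 0.21), S100a10 (-1.21 ± 0.25), Rpl22l1 (-1.20 ± 0.26), Atp5md (-1.17 ± 0.28) and Gm6607 (-1.14 ± 0.19) fell. Ribosomal protein genes fell in 22 of 39 (33 adjusted over the list alone, median -0.55; adjusted p = 0.157 with an estimated correlation). That median was -0.19 without TG animal 1 at 17 dpi and -0.28 without TG animal 21. Skeletal muscle genes rose in 1 of 16 (1 adjusted over the list alone, median 1.09; adjusted p = 0.0112 at the preset correlation and 0.601 with an estimated one). TG animals 21 and 27 at 80 dpi are those with high muscle genes, and without them and animal 1-5 that median was -0.24. It was 0.32 without TG animal 1 at 17 dpi and 0.62 without TG animal 21. In all 2854 probes rose and 1782 fell, and the total was 24 without TG animal 1 at 17 dpi, 8075 without TG animal 3, and 137, 393 and 2137 without TG animals 21, 27 and 26 at 80 dpi.

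**Figure D3:**
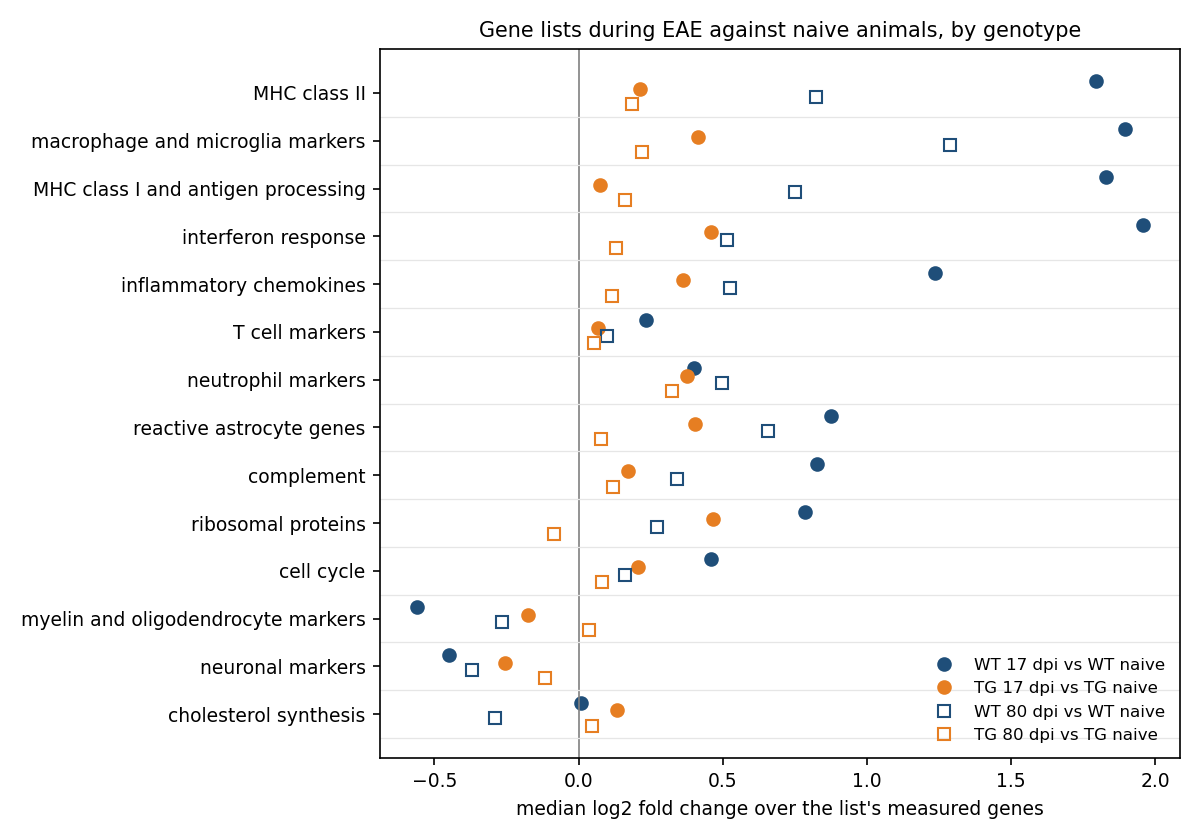
Median log2 fold change (horizontal axis) of 14 gene lists (vertical axis) in EAE against naive cord; filled circles are 17 dpi and open squares 80 dpi, blue is WT and orange TG. Macrophage and microglia markers are at 1.89 in WT and 0.42 in TG at 17 dpi, and at 1.29 and 0.22 at 80 dpi.

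Whether the EAE change differed between genotypes was tested as an interaction. From naive to 17 dpi it differed in 848 probes upward in TG and 2063 downward. The smallest p belonged to Rnf149 (-1.56 ± 0.12), Chil4 (-3.68 ± 0.31), the receptor Notch2 (-1.27 ± 0.11), the lipid antigen presenter Cd1d1 (-1.75 ± 0.16) and Nhlrc3 (-0.96 ± 0.09). Macrophage and microglia markers were lower in 32 of 41 (34 adjusted over the list alone, median -1.43; adjusted p = 0.115 with an estimated correlation). From naive to 80 dpi 7 probes differed upward and 147 downward, led by Gpnmb (-4.25 ± 0.37), the growth factor Igf1 (-1.07 ± 0.10), Ctsd (-2.51 ± 0.23), Rpp25l (-1.70 ± 0.15) and Col1a2 (-1.22 ± 0.11). Macrophage and microglia markers were lower in 15 of 41 (30 adjusted over the list alone, median -1.03) and cholesterol synthesis genes higher in 4 of 20 (15 adjusted over the list alone, median 0.38), both also with an estimated correlation (adjusted p = 0.0282 and 0.0204). From 17 to 80 dpi 512 probes differed upward and 195 downward, led by Chil4 (3.94 ± 0.29), Igf1 (-1.26 ± 0.10), the growth factor binding protein Igfbp5 (-1.82 ± 0.15), Cd1d1 (1.70 ± 0.15) and the microglial receptor Fcrls (-2.13 ± 0.19). From naive to 10 dpi limma called 0 probes, with 2002 at an unadjusted p under 0.05. The most extreme were Efcab11 (-0.64 ± 0.10), Panx3 (-1.40 ± 0.21), Tmprss11g (0.58 ± 0.11), Ccnd2 (-0.65 ± 0.13) and Peg10 (0.84 ± 0.17), none of which passed. A moderated F test over all coefficients called 6674 probes. With 1 animal left out the first 3 interaction counts ranged from 488 to 6458, from 19 to 156 and from 54 to 1835, the lowest without naive TG animal 5, naive TG animal 8 and TG animal 1 at 17 dpi.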

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

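Of the tests in this part, those of dye bias, of outside tissue, of title order and of a labelling batch at 10 dpi were chosen after the result was seen. The outside tissue test replaced an earlier version on 1 animal once that had been run. The closed loop test was added after the others, with its bounds set before it was run. The rest were fixed beforehand.

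In 86 groups of 4 arrays examined, 7 had 1 array far from the other 3 by Dixon's criterion at the 95% level. The 86 include Panx3 at 10 dpi, which had a value on 1 array only and could not be tested. Chance alone singles out about 1 in 20. The groups share arrays, animals and genes, so the 7 are not separate events and cannot be weighed against that share. After removal of the dye effect, the 10 dpi array of TG animal 1-3 and WT animal 10-4 stood apart in 4 lists. Its medians, TG over WT, were -1.51 for inflammatory chemokines (others -0.25 to -0.11), -0.51 for inflammatory cytokines (others -0.09 to -0.02), -1.39 for macrophage and microglia markers (others -0.17 to -0.08) and -1.01 for reactive astrocyte genes (others -0.18 to -0.03). At 80 dpi Hbb-bt was 0.42 on the array of TG animal 26 and WT animal 13, against 1.23 to 1.35 on the others. On the array of TG animal 27 and WT animal 14, Trem2 was -2.52 and Tyrobp -2.27, against -2.02 to -1.97 and -1.96 to -1.90.

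The 10 dpi array that stood apart was set against the WT change from naive to 17 dpi. Its profile over the 3744 genes called there correlated at -0.804 with that change, across genes, which are not independent replicates. A batch effect shared by arrays of that dye orientation is argued against, since the other such array had an interferon median of -0.305 where this one had -2.07. The direction of that other array is the least secure. A labelling fault of this array alone would leave no trace there and was not tested. A candidate explanation is that the WT animal of the pair was further along in EAE than the TG animal. The test leaves it open, because the other 3 arrays gave -0.313, 0.126 and -0.302, wider than that explanation had been set to allow.

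The EAE change differed between genotypes by an interaction test in 2911 probes for 17 dpi against naive, 154 for 80 dpi against naive and 707 for 80 against 17 dpi. For 17 dpi against naive the smallest p belonged to Rnf149 (-1.56), Chil4 (-3.68), Notch2 (-1.27), Cd1d1 (-1.75) and Nhlrc3 (-0.96). For 80 dpi against naive it belonged to Gpnmb (-4.25), Igf1 (-1.07), Ctsd (-2.51), Rpp25l (-1.70) and Col1a2 (-1.22). For 80 against 17 dpi it belonged to Chil4 (3.94), Igf1 (-1.26), Igfbp5 (-1.82), Cd1d1 (1.70) and Fcrls (-2.13). Among lists, only those that passed with both a preset and an estimated correlation are given, a restriction made after the counts were seen: for 80 dpi against naive, macrophage and microglia markers at -1.03 and cholesterol synthesis genes at 0.38. At the preset correlation alone 18 of 28 lists passed for 17 dpi against naive, 24 for 80 dpi against naive, 17 for 80 against 17 dpi and 17 for 10 dpi against naive.

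Macrophage and microglia markers, MHC class II genes, chemokines and complement genes were lower in TG than in WT at 17 and 80 dpi at the preset correlation, neutrophil markers were not, and of those lists with an estimated correlation macrophage and microglia markers at 80 dpi alone passed (adjusted p = 0.0289). As read, the highest macrophage and microglia median over the 7 arrays in both dye orientations was -0.797. In title order an equal sign in both orientations is what a dye effect gives. That value alone therefore argues against dye bias only if the reading holds. On the naive arrays, of both dye orientations, the deposited median was -0.01 to 0.02. A dye effect alike on all arrays would show there in either reading, so those values argue against it. A dye effect particular to the 17 and 80 dpi arrays is not excluded in title order. Under the reading used, dilution by muscle or blood is argued against by the highest difference of the macrophage and microglia median minus the neuronal one, -1.03. A single animal is argued against at 80 dpi, where the highest median with 1 animal left out was -0.95, and without the 3 muscle-rich TG animals, which leaves 1 TG animal at 80 dpi, it was -0.93. Title order was examined by 2 closed loops of 12 arrays, as a set, for the 5 of them that the readings treat differently. Their sums less the dye effect, estimated under each reading, argue against title order. They had spreads of 0.364 and 1.02 as used and 0.536 and 1.42 in title order (higher ratio 0.717). The uncorrected sums went the other way (0.783 and 1.62, against 0.318 and 0.887), and the lowest spreads of all were those of title order uncorrected. The verdict thus depends on the correction, and the loops do not settle the reading. The log-likelihood difference of 57710 had served to choose the reading. Less infiltration or activation of phagocytes in TG cord may be put forward as a hypothesis only, found and examined on the same arrays, and the direction of the TG and WT arrays at 17 dpi is outside the loops.

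Ribosomal protein genes rose at 17 dpi in both genotypes, with medians of 0.79 in WT (1.31 without WT animal 1) and 0.47 in TG (0.185 without TG animal 1), calls that were lost with an estimated correlation (adjusted p = 0.125 and 0.238). RNA quality was read as a trend of the change with genomic gene length. The Spearman correlations over genes were -0.058 in WT and -0.0685 in TG, short of the bound set beforehand for such a trend (0.102 for TG against WT at 80 dpi, which this pattern does not hold). That length spans introns and is not the length of the transcript, so the test cannot decide on RNA quality. Infiltrating cells as the only source would put the ribosomal median higher in WT at 80 dpi than in TG at 17 dpi. The lowest difference, TG at 17 dpi minus WT at 80 dpi with 1 animal left out, was -0.0856, and the full fit gave 0.47 and 0.27, so that source stays open. Other effects of RNA quality that do not follow gene length may also contribute and were not tested.

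Other divisions of the same animals into groups of equal size were fitted for the counts that compare 3 with 3 animals. They number 10, too few for a share under 0.05. For TG against WT in naive mice the real division gave 0 probes and the highest other 21. All 10 divisions reached the real count, as any division reaches 0, so that share says nothing on chance. At 10 dpi 7 of 10 divisions reached the real count (12 against 528), so it does not set the real division apart. Why other divisions gave more probes was not tested, and a ratio read in the wrong direction at 10 dpi is not excluded as part of the reason. The real division was the highest, 1 of 10, at 80 dpi (726 against 0), for WT at 80 dpi against naive (476 against 0), for TG at 17 dpi against naive (7299 against 1999), for TG at 80 dpi against naive (9 against 0) and for TG at 80 against 17 dpi (4636 against 0). For the interaction of 80 dpi with naive 1 of 100 drawn divisions, the real one, reached the real 154 (highest other 139). The ratio directions were chosen in part by the fit with the real groups and were held in every division. That can favour the real division, so chance is not excluded by that share. For 10 dpi with naive all 100 reached the real 0 (highest other 88), which any division does, so that share decides nothing. WT at 17 dpi has 2 animals, so contrasts and interactions that use it were not examined this way.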

How the results depend on the processing

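Title order for all arrays, title order at 10 dpi alone, the separate dye term at 10 dpi and the fit without TG animals 1-5, 21 and 27 were chosen after the data were seen. The other settings were planned. Counts stayed within 1.5 times the reported ones when arrays were treated as independent or recentred, with complete probes, with no probe minimum and with robust moderation. Treating arrays as independent or recentring them could hardly move a count. The fitted correlation was already 0.01 and the array medians lay between -0.02 and 0.02. Those settings therefore say little on the repeated use of an animal. The 169 values of named genes past the threshold kept their sign in each planned setting, except for 3 of 1032 with 1 animal left out (below). They were chosen as extreme on the same arrays, so kept signs are little evidence. How many stayed past the threshold is given below. Where a count or sign moved, the cause was not tested, except that averaging per gene tests fewer items and leaving out animals or arrays uses fewer samples. Deposited ratios carry no signal over background, so its limits could not be examined. No paired analysis was possible because groups that are compared share at most 1 animal number, so numbers could not serve as a block. The pairing of 2 animals on an array is part of every fit, and the arrays that pair the groups directly are given alone below.

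Counts of called probes are given for TG against WT, then within WT, within TG, for the interactions and for the moderated F. As reported they were 0, 12, 5678 and 726 from naive to 80 dpi, 7058, 476 and 3407 in WT and 7299, 9 and 4636 in TG (17 and 80 dpi against naive, then 80 against 17 dpi), 2911, 154 and 707 for the interactions in that order, 0 for the interaction of 10 dpi with naive, and 6674. Without the dye term they were 0 at 10 dpi, 2195 at 17 dpi and 409 at 80 dpi, 4233, 265 and 1431 in WT, 1425 (17 dpi against naive) and 597 (80 against 17 dpi) in TG, 1051, 89 and 262 for the interactions and 2467. With recentred and scaled arrays they were 22 at 10 dpi, 2901 at 17 dpi, 4238 in WT at 17 dpi, 4608, 17 and 1171 in TG, and 1517, 232 and 355. That scaling moved the split of higher and lower calls from 6 and 6 to 8 and 14 at 10 dpi, from 1989 and 3689 to 714 and 2187 at 17 dpi, from 428 and 48 to 557 and 148 in WT at 80 dpi against naive, and from 512 and 195 to 219 and 136 for the interaction of 80 with 17 dpi. With array weights they were 251, 3, 11798 and 8723 from naive to 80 dpi, 13274, 4781 and 14060 in WT, 20027, 5853 and 18955 in TG, 12857, 7900, 7871 and, for 10 dpi against naive, 6, and 27199. With probes averaged per gene they were 0, 2858 and 481 from 10 to 80 dpi, 3744 and 1929 in WT (17 dpi against naive, 80 against 17 dpi), 2968 and 1761 in TG, 1418 and 364, and 3417. The arrays pairing the groups alone gave 133, 0, 0 and 1244 from naive to 80 dpi.

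In title order the counts were 3807, 3480, 0 and 9964 from naive to 80 dpi, 0, 0 and 0 in WT, 29, 0 and 2 in TG, 0, 0 and 0 for the interactions and 1002 for 10 dpi against naive. With title order at 10 dpi alone they were 2308 and, for the interaction, 750. The macrophage and microglia, MHC class II, interferon and chemokine medians at 10 dpi turned to 0.40, 0.39, 0.69 and 0.65, Lratd1 to -0.28, Ddx58 to 0.32 and Smc6 to 0.19. A separate dye term at 10 dpi gave 0 calls there. Without the 3 muscle-rich TG animals the counts were 0, 401 and 0 from 10 to 80 dpi, 1458, 49 and 16 in WT, 791, 0 and 0 in TG and 29, 0 and 0, and the skeletal muscle median turned to -0.186 at 10 dpi, -0.0336 at 80 dpi and, for TG at 80 dpi, -0.0722 against naive and -0.24 against 17 dpi.

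Values that changed sign in title order are given here, for TG against WT unless said otherwise. For TG against WT in naive mice the myelin median was 0.025. At 10 dpi the medians were macrophage and microglia 0.34, MHC class II 0.30, interferon 0.62, muscle -0.00423 and chemokine 0.62, and the genes were Lratd1 -0.28, Ddx58 0.31 and Smc6 0.22. At 17 dpi the medians were macrophage and microglia 0.15, MHC class II 0.0973, complement 0.0585, T cell 0.17, NF-kappaB 0.0835, neuronal -0.17, red blood cell -0.00966, cell cycle 0.11 and myelin -0.0649, and the genes were Rspo4 -0.22, H2-Ab1 0.0252, Lyz1 0.0932 and Gpnmb 0.80. At 80 dpi the medians were macrophage and microglia 0.42, MHC class II 0.43, cholesterol -0.21, muscle -0.31, neuronal -0.29, reactive astrocyte 0.30, homeostatic astrocyte 0.10, matrix and scar 0.14, complement 0.27, chemokine 0.30, red blood cell -0.10 and B cell 0.20, and the genes were Insig1 -0.80, Hmgcs1 -0.14, Hbb-bt -0.40, Idi1 -0.66, Stard4 -0.70, Cyp51 -0.49, Fdps -0.46, Lratd1 -0.59, Nefm -0.87, Msmo1 -0.0857, Gpnmb 2.35, Lyz1 2.12, Lyz2 1.84, Trem2 1.42, Ctsd 1.48, Ctss 0.98, Tyrobp 1.32, C1qa 1.04, H2-Ab1 1.53, C1qc 1.03, Gfap 0.49 and 0.50. In WT at 17 dpi against naive the medians were macrophage and microglia -0.82, MHC class II -0.80, ribosomal -0.12, interferon -0.43, MHC class I -0.40, neuronal 0.18, myelin 0.33, neutrophil -0.56, cell cycle -0.33, cytokine -0.37, chemokine -0.37 and precursor 0.000407, and the genes were Cxcl10 -0.0457, Iigp1 -0.16, Gbp3 -0.51, Lyz1 -1.59, AW112010 -0.13, Wfdc17 -0.92, H2-Ab1 -1.28, Ctsc -0.80, Tgtp1 -0.0993, Gm14461 2.81, Snap25 0.72, Ndrg4 0.71, Vps26b 1.07, Lmtk2 0.20 and Thoc2 1.45. In WT at 80 dpi against naive the medians were macrophage and microglia -1.31, MHC class II -0.86, cholesterol 0.0749, neuronal 0.22, neutrophil -0.28 and Schwann cell -0.13, and the genes were Lyz1 -2.77, S100a8 -0.75, Gpnmb -2.90, Lyz2 -2.18, S100a9 -0.0429, Serping1 -1.69, Cfhr2 -1.40, H2-Ab1 -2.27, Wfdc17 -2.80, Hmgcs1 0.31, Fdps 0.30, Gng3 0.71, Slc17a6 0.0124, Slc25a33 0.22, Eef1a2 1.12, Tsc22d3 0.0221 and Kcnh1 0.33. In TG at 17 dpi against naive the medians were macrophage and microglia -0.21, neuronal 0.0739 and neutrophil -0.24, and the genes were Cfhr2 -0.46, Rbm3 -0.15, Agbl4 -0.24, Ndrg4 0.27 and Lmtk2 0.0856. In TG at 80 dpi against naive the macrophage and microglia median was -0.18. For the interaction of 17 dpi with naive the macrophage and microglia median was 0.64, and the genes were Rnf149 0.13 and Notch2 0.083. For the interaction of 80 dpi with naive the medians were macrophage and microglia 1.00 and cholesterol -0.18, and the genes were Gpnmb 2.99, Igf1 0.65, Ctsd 1.55, Rpp25l 0.82 and Col1a2 1.1. For the interaction of 80 with 17 dpi the genes were Igfbp5 0.19 and Fcrls 0.16.

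With 1 animal left out the counts ranged from 0 to 0 in naive mice, 6 to 44 at 10 dpi, 2796 to 11748 at 17 dpi and 158 to 333 at 80 dpi. In WT they ranged from 983 to 12775, 58 to 474 and 696 to 7118, and in TG from 14 to 11113, 1 to 7 and 24 to 8075. For the interactions they ranged from 488 to 6458, 19 to 156, 54 to 1835 and, for 10 dpi, 0 to 3, and for the moderated F from 2676 to 11059. Gm14461 in WT at 17 dpi turned to 0.11 and 0.22, Rspo4 at 17 dpi to -0.16 and the neutrophil median in WT at 17 dpi to -0.0726 and -0.0519. The muscle median at 10 dpi ranged from -0.186 (without TG animal 1-5) to 1.83. Where 1 animal of a group was left, it was assumed to vary like the other groups.

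Named values past the threshold stayed past it in 136 of 169 without the dye term, 149 with scaled arrays, 162 with array weights, 152 per gene, 758 of 1032 with 1 animal left out, 40 of 168 without the muscle-rich animals and 20 of 45 on the direct arrays. In title order 1 of 169 stayed past it and 75 changed sign. Of 250 list calls, counting lists not described in the text, 184 changed sign in title order, 2 changed sign with scaled arrays, 2 with array weights and 8 without the muscle-rich animals, as did 32 of 39 in title order at 10 dpi and 23 of 1862 with 1 animal left out. Of 76 list medians described in the text or shown in its figures that were called, 36 moved by over 1.5 times or turned with some animal left out.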

Other observations

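The lists and values in this part were chosen for description after they were seen, and no further test was made here. Meningeal, choroid plexus and ependymal genes rose in 3 of 15 in WT cord at 80 dpi against naive (7 adjusted over the list alone, median 0.15), among them Igf2 (3.07 ± 0.25) and the sulphate transporter Slc13a4 (0.72 ± 0.12). Against 17 dpi they rose in 5 and fell in 1 (6 and 1 adjusted over the list alone, median 0.18), with the prostaglandin synthase Ptgds at 1.80 ± 0.32. Schwann cell and nerve root markers rose in 2 of 10 in WT cord at 80 dpi against naive (4 adjusted over the list alone, median 0.27), namely Ncmap (1.23 ± 0.18) and Pmp22 (0.60 ± 0.10). From 17 to 80 dpi endothelial and pericyte markers rose in 10 of 21 in WT and fell in 1 (15 and 1 adjusted over the list alone, median 0.56), with the cadherin Cdh5 at 0.70 ± 0.12, Abcc9 at 0.85 ± 0.16 and Ly6c1 at -1.69 ± 0.27. In TG 8 rose (11 adjusted over the list alone, median 0.38), with the tight junction gene Cldn5 at 0.96 ± 0.19. Over the same interval mitochondrial respiratory chain genes fell in 14 of 38 in WT and rose in 1 (17 and 2 adjusted over the list alone, median -0.61), with Ndufa5 at -0.89 ± 0.13, and fell in 11 and rose in 1 in TG (18 and 2 adjusted over the list alone, median -0.41). Without WT animal 14 at 80 dpi, naive WT animal 2 or naive WT animal 4 the first meningeal median was 0.0881, 0.0683 and 0.0774, and without WT animal 1 at 17 dpi the second was 0.29. The mitochondrial median in TG was -0.0993 without TG animal 1 at 17 dpi. These 7 list calls passed at the preset correlation and were lost with an estimated one (adjusted p = 0.119, 0.178, 0.119, 0.119, 0.155, 0.253 and 0.277 in the order given).

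In WT cord at 17 dpi against naive, cell cycle genes rose in 13 of 25 and fell in 1 (13 and 1 adjusted over the list alone, median 0.46), with Mki67 at 1.32 ± 0.25 and the mitotic kinase Aurkb at 2.16 ± 0.43. Inflammatory cytokines rose in 9 of 21 (11 adjusted over the list alone, median 0.53), including Ifng (0.80 ± 0.15) and Tgfb1 (1.20 ± 0.22), and oligodendrocyte precursor markers fell in 5 of 12 (6 adjusted over the list alone, median -0.15). Subunits of NADPH oxidase were lower in TG than in WT at 17 dpi in 4 of 7 (4 adjusted over the list alone, median -1.33), with Ncf1 at -1.33 ± 0.18 and Ncf4 at -1.58 ± 0.21. Immediate early and glucocorticoid response genes were lower in 4 of 22 (7 adjusted over the list alone, median -0.23), with Sgk1 at -0.60 ± 0.10 and Egr2 at -1.16 ± 0.29. B cell and plasma cell markers were lower in TG at 80 dpi in 3 of 16 (4 adjusted over the list alone, median -0.08), with the adaptor Blnk at -1.36 ± 0.15 and the immunoglobulin joining chain Jchain at -0.86 ± 0.10. Without WT animal 1 at 17 dpi the medians in WT were 0.14 for cell cycle genes, 0.19 for cytokines and -0.30 for precursor markers, and without naive WT animal 2 the first 2 were 0.24 and 0.29. The NADPH oxidase median was -0.38 without TG animal 7 and -0.62 without WT animal 1, and that of immediate early genes -0.12 without WT animal 1. These 6 calls at the preset correlation were also lost with an estimated one (adjusted p = 0.232, 0.206, 0.119, 0.178, 0.212 and 0.154). Lratd1 was above 0, TG over WT, on all 14 arrays that pair the genotypes, from 0.09 to 2.44. Some animals are on more than 1 of these arrays.

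The array of TG animal 3 and WT animal 4 at 17 dpi had an array weight of 0.0389. The 3 arrays of TG and WT at 17 dpi correlated with each other over probes at -0.138, -0.0479 and 0.238.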
